A study of Mus musculus with 16 samples.

How the data were processed

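RNA from 16 samples of mouse colon organoids was measured with single-colour Affymetrix arrays, 1 array per sample. Per the labels' protocols, organoids grew in ENR medium (EGF, Noggin and R-spondin), 400 ng of total RNA was amplified, and the product was labelled with biotin. The labels give the TNFa treatment, 50 ng/ml for 12 h, in the protocol of every sample, but only the samples whose own titles and characteristics name TNFa were taken as treated. The mutant samples carry labels that contradict each other on which of Atf2 and Atf7 was knocked out and which was floxed, so they were kept as 1 genotype. No label says whether the floxed allele was recombined, so whether both genes were lost is not known. The titles number the samples 1 to 4 in each of 4 groups, and no label says what a number stands for.

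Per the submitters' processing notes, the authors computed the deposited values with RMA in Affymetrix Expression Console, and the deposited values are log2 signals. The versions of these tools, the array design and the genome build were not given in the sources used here. The values fit that unit: they ran from 2.23 to 12.9 log2, the array medians from 7.02 to 7.11, and 100% of the values were logarithms of a linear signal rounded to 1 decimal. Of 19825 probe sets, 18851 carried a single gene symbol, 974 carried none and 0 carried several. No probe set was named Atf7.

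Each of 18850 genes was represented by its probe set with the highest mean. A gene was tested if its signal was above its array's 40th percentile, which lay between 6.40 and 6.56 log2, on at least 4 of the 16 arrays. This left 11766 genes and set aside 7084 dim ones. Tested genes can still be dim in some groups, and named changes were checked for a group mean below 6.56 log2, the highest of these percentiles, where a fold change is approximate. No further normalization was applied. Group means were compared in limma 3.58.1 under R 4.3.3, with 1 fit to all 16 arrays and moderated t-tests, and Benjamini-Hochberg adjusted p under 0.05 was called. The comparisons were the TNFa effect in WT, the TNFa effect in mutant, the genotype effect without TNFa, the genotype effect with TNFa, and the difference of the TNFa effects. Errors are the SE of the fit, SD is between the 4 arrays of a group, and intervals cover 95%.

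Gene lists were written from general knowledge before the data were examined, as were the comparisons, the filter, the thresholds, the rule for naming genes and the alternatives. There were 25 lists with 628 members, of which 557 were on the array and 448 tested. They were NF-kB targets, chemokines, interferon response, antigen presentation, antimicrobial and oxidase genes, AP-1, ATF and MAPK feedback, cell death machinery, p53 targets, stem cell and Wnt targets, proliferation, absorptive colonocyte, goblet cell, enteroendocrine cell, tuft cell, wound-associated and fetal-like epithelium, junctions and barrier, unfolded protein and integrated stress response, cholesterol synthesis, oxidative stress and glutathione, distal hindgut patterning, small intestine and Paneth cell, fibroblast and smooth muscle, immune cell, endothelial and glial, and sex-linked genes. The sex-linked genes served only as a check of the samples. The other 24 were tested with camera at a preset inter-gene correlation of 0.01, adjusted over all 120 tests, and again with the correlation estimated. Counts over the list alone adjust p over the list's own members.

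Genes were named by a rule. In the 4 simple comparisons these were the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap, and in the difference of TNFa effects up to 6 called genes each way. Up to 4 called genes with the smallest p were added per list and comparison, and Atf2 and Atf7 were always to be named. Genes outside this rule are members of a list whose moves the text describes or neighbours of Atf2, chosen after their values were seen. Fold changes are given as sizes with the direction in words.

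The functions were tested on simulated arrays with 200 changed genes among 11766. Changes of 1 log2 were recovered for 97 to 100% of genes in all 5 comparisons. Changes of 0.5 log2 were recovered for 84% of genes for TNFa in WT and 85% for TNFa in mutant. For the genotype effect the shares were 80% without TNFa and 87% with it, and for the difference of TNFa effects 52%. All these shares hold for 200 changed genes, and the adjusted threshold is stricter where fewer genes change. In the real data the difference of TNFa effects called 1 gene, so larger changes can be missed there as well. Il1a, dim without TNFa, differed by 0.94 log2 and was not called. False calls numbered 3 to 11.

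The alternatives were no filter, a stricter filter at the 60th percentile, the mean of a gene's probe sets, every probe set on its own, a variance trend with robust fitting, array weights, centring on array medians, quantile normalization again, a minimum change of 2-fold, blocks for the sample numbers, leaving out each array in turn, fitting only the 2 groups compared, the estimated correlation and the fry test for lists, the Spearman correlation, and other thresholds for the size of the response. Settings chosen after the data were seen were leaving out array WT + TNFa 2, the size of the response over genes with no dim group, and the Paneth list with its defensin and lysozyme copies merged in the simple comparisons. The size of the TNFa response was compared with fry over genes whose change, averaged over the genotypes, passed a threshold. Chance was tested with all 35 splits of the 8 arrays of a simple comparison, and with 100 splits for the difference of TNFa effects, the real one included and the others drawn at random with the genotypes exchanged within each treatment. Gene neighbourhood was taken from the RefSeq gene order of assembly GRCm38.p6, with tested genes placed by gene identifier and Atf2 and Atf7 by symbol.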

Results

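Gene expression was measured on arrays in mouse colon organoids, cultured balls of colon epithelium, with and without tumour necrosis factor alpha (TNFa), a cytokine of intestinal inflammation. The 16 arrays formed 4 groups of 4: wild-type (WT) organoids, WT organoids given TNFa at 50 ng/ml for 12 h, mutant organoids labelled for altered alleles of both Atf2 and Atf7, and mutant organoids given TNFa. ATF2 is a transcription factor of the AP-1 and CREB families that the stress kinases JNK and p38 phosphorylate, and ATF7 is its close relative. The labels of the mutant samples contradict each other on which of the genes was knocked out and which was floxed. No label says whether the floxed allele was recombined, so it is not known that both genes were lost. No label says that the numbered samples came from separate animals or separate cultures, so the p-values measure the spread between these samples, and how much of it is technical is not known. Of 18850 named genes, 11766 were bright enough to be tested. Signals below 6.56 log2 lay in the dim range, and a fold change with a group mean in that range is approximate. Array WT + TNFa 2 stood apart from its group, with a mean correlation of 0.977 with the other arrays of the group against 0.986 to 0.988 for those, and its median of 7.11 log2 was the highest of the 16.

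Atf2 mRNA did not differ between the genotypes. Its signal, from 1 probe set, was 10.16 ± 0.14 log2 in WT (mean ± SD, n = 4), 10.18 ± 0.02 in WT with TNFa, 10.15 ± 0.03 in mutant and 10.12 ± 0.01 in mutant with TNFa. The mutant was 0.02 log2 lower without TNFa (SE 0.06, 95% interval −0.15 to 0.11, adjusted p = 0.942) and 0.06 lower with it (adjusted p = 0.729). Which part of Atf2 the probe set covers is not given in the sources used here, and a probe set outside a deleted part keeps its signal, so these values check neither the knockout nor the floxed state. TNFa left Atf2 unchanged in WT (0.01 log2, adjusted p = 0.926) and in mutant (−0.03, adjusted p = 0.917), and the difference of these effects was −0.04 (SE 0.09, adjusted p = 0.945). Atf7 had no named probe set and was not analysed here.

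In WT organoids, TNFa strongly raised an inflammatory epithelial program. Ccl20, a chemokine that attracts CCR6-bearing lymphocytes and dendritic cells, rose 17.7-fold (4.15 log2, SE 0.11, adjusted p = 2.3e-13, n = 4 per group), from 7.30 ± 0.21 to 11.45 ± 0.14 log2. Nos2, the inducible nitric oxide synthase, rose 12.8-fold (3.67 log2, SE 0.17, adjusted p = 5.4e-10) from a dim 6.40 ± 0.16 log2. The steepest falls were in gasdermin C genes, a family of pore-forming proteins: Gsdmc3 fell 5.45-fold (−2.45 log2, SE 0.17, adjusted p = 3.9e-08), Gsdmc4 4.93-fold (−2.30) and Gsdmc2 4.66-fold (−2.22), although such similar genes can share probes and Gsdmc3 and Gsdmc2 fell into the dim range. In all, 592 genes rose and 677 fell, and 59 of the rises and 29 of the falls were at least 2-fold. Other large rises were those of Csf1, the macrophage growth factor (4.41-fold), Clca4b, a chloride channel regulator (3.99-fold), Ecscr, first described in endothelial cells (3.96-fold), Il5ra, an interleukin 5 receptor chain (3.94-fold), Tnfaip3, which encodes the NF-kB inhibitor A20 (3.83-fold), and Far2, a fatty acyl-CoA reductase (3.69-fold). Among the falls were the aldo-keto reductase Akr1c14 (3.11-fold), the zinc transporter Slc39a5 (2.90-fold), the sphingolipid synthesis gene Sptssb (2.88-fold), the cytochrome P450 gene Cyp2b10 (2.52-fold) and the urea cycle enzyme Otc (2.52-fold). Of the 30 named changes of at least 2-fold in WT, 11 had a group in the dim range, those of Ecscr, Il5ra, Sptssb, Cyp2b10 and Otc among them.

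In WT 9 of 24 lists were called, 7 up and 2 down. As many were called in 7 of 35 splits of these arrays, the real one included. The number of called lists therefore does not exclude chance, and the same held in the other comparisons. Of 24 NF-kB targets, 18 rose and 0 fell over all genes, or 20 and 2 adjusted over the list alone (median 0.63 log2, adjusted p = 3.6e-23). The NF-kB subunit gene Nfkb2 rose 2.05-fold, Nfkbia, which encodes the inhibitor IkBa, 2.49-fold and the apoptosis inhibitor Birc3 2.01-fold. Of 11 chemokines, 6 rose and 0 fell, or 6 and 1 over the list alone (median 0.65, adjusted p = 1.2e-07), among them Cxcl16 (2.41-fold), Cxcl10 (2.28-fold) and Cxcl11 (3.28-fold). Cxcl10 and Cxcl11 rose from the dim range. Of 16 antigen presentation genes 7 rose and 0 fell, or 10 and 0 over the list alone (median 0.22, adjusted p = 3.1e-05), as with the peptide-editing gene Tapbpl (1.42-fold) and the immunoproteasome gene Psmb9 (1.40-fold). Of 14 antimicrobial and oxidase genes 7 rose and 1 fell, the same over the list alone (median 0.29, adjusted p = 2.2e-06), with the NADPH oxidase Nox1 at 2.44-fold and the dual oxidase maturation factor Duoxa2 at 3.29-fold, while the cytokine Il18 fell. The interferon response list rose (median 0.23, adjusted p = 0.010), with 4 of 16 genes up and 1 down, or 5 and 1 over the list alone, but adjusted p = 0.194 with an estimated correlation. Isg15, a ubiquitin-like antiviral protein (1.90-fold, from the dim range), and the RNA sensor Ddx58 (1.81-fold) rose. Of 33 cell death genes 9 rose and 2 fell, or 14 and 2 over the list alone (median 0.15, adjusted p = 0.00141), with the death ligand Tnfsf10 at 2.51-fold, from the dim range, and the inflammatory caspase Casp4 at 1.78-fold. The fallen members of that list, Gsdmc4 and Gsdmc2, encode pore formers and so moved against the list, which had adjusted p = 0.133 with an estimated correlation. Wound-associated and fetal-like genes rose (7 of 26 up and 0 down, 10 and 0 over the list alone, median 0.19, adjusted p = 1.1e-05; adjusted p = 0.149 with an estimated correlation). Members that rose were the integrins Itgb6 (2.22-fold) and Itga2 (1.71-fold) and the laminin chain Lama3 (1.67-fold). Goblet cell genes fell (1 of 25 up and 7 down, 1 and 9 over the list alone, median −0.11, adjusted p = 3.3e-04; adjusted p = 0.268 with an estimated correlation). Reg4, a secreted lectin of goblet and other secretory cells, fell 1.69-fold (−0.75 log2, SE 0.07, adjusted p = 1.6e-06), whereas the mucin-modifying St6galnac1 rose 1.91-fold. Small intestine and Paneth cell genes fell (0 of 19 up and 3 down, 0 and 9 over the list alone, median −0.25, adjusted p = 6.3e-04). The fallen genes were the purine enzyme Ada (1.58-fold), the lysozyme gene Lyz1 (1.67-fold) and the lipoprotein assembly gene Mttp (1.36-fold). With the defensin and lysozyme copies counted as 1 gene the list kept its call (adjusted p = 0.0106).

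The other 15 lists were not called in WT, but single members moved. Of 28 absorptive colonocyte genes 6 rose and 5 fell (median 0.02, adjusted p = 0.646). Guca2b, which encodes uroguanylin, a ligand of guanylate cyclase C, rose 3.15-fold (1.65 log2, SE 0.07, adjusted p = 4.5e-11) and its relative Guca2a 2.08-fold, whereas the fatty acid binding protein gene Fabp2 fell 2.23-fold. In the distal hindgut patterning list the homeobox genes Hoxd13 (2.06-fold) and Hoxd11 (1.65-fold) rose and 0 of 8 fell (adjusted p = 0.201). Of 19 stem cell and Wnt targets 4 rose and 0 fell, with the adhesion receptor Cd44 at 1.76-fold and the ion cotransporter Slc12a2 at 1.64-fold. The median (−0.02 log2) and the mean (0.07) had opposite signs and the list was not called (adjusted p = 0.550). Of 19 enteroendocrine genes 3 rose and 3 fell, or 3 and 5 over the list alone (median −0.10, adjusted p = 0.598). The serotonin synthesis genes Tph1 and Gch1 and the prohormone processing gene Cpe rose, while Scg2, Chga and Pyy fell. None of 30 proliferation genes passed and the list was not called (adjusted p = 0.268), but it was called as higher without WT + TNFa 2 (mean 0.13 log2, adjusted p = 0.00541) or WT 2 (0.0467). In the AP-1, ATF and MAPK feedback list 2 of 30 rose and 1 fell (adjusted p = 0.936) and in the p53 list 3 of 20 rose (adjusted p = 0.125, or 0.0375 without WT + TNFa 2). In the unfolded protein and integrated stress response 2 of 28 fell (adjusted p = 0.714) and in cholesterol synthesis 1 of 19 fell (adjusted p = 0.646). The number of called genes went from 1269 to 720 when only the WT arrays were used. The interferon list lost its call without array WT + TNFa 4 (adjusted p = 0.0534), and Ada, Lyz1 and Mttp lost theirs without 3, 4 and 13 of the 16 arrays in turn, with adjusted p up to 0.0599, 0.0892 and 0.148. The risen p53 targets Fas, Pmaip1 and Aen lost theirs without 5, 9 and 14, with adjusted p up to 0.119, 0.133 and 0.146.

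In mutant organoids TNFa raised Ccl20 and Nos2 most, as in WT. Ccl20 rose 19.0-fold (4.25 log2, SE 0.11, adjusted p = 1.6e-13, n = 4 per group), Nos2 18.9-fold (4.24 log2, SE 0.17, adjusted p = 7.7e-11), and Il1a, the cytokine interleukin 1 alpha, 6.94-fold (2.80 log2, SE 0.15, adjusted p = 1.3e-09). Tnf itself rose 5.02-fold, from 6.58 ± 0.38 to 8.91 ± 0.12 log2. The gasdermin C genes again led the falls, with Gsdmc2 down 4.06-fold, Gsdmc3 4.00-fold (SE 0.17 log2, adjusted p = 4.5e-07) and Gsdmc4 3.76-fold. In all, 413 genes rose and 291 fell, 52 and 16 of them at least 2-fold. Far2 (4.94-fold), the copper oxidase ceruloplasmin, Cp (4.90-fold), Clca4b (4.87-fold) and the GABA receptor subunit Gabrp (4.49-fold) were also among the largest rises. The pseudogene Trim30e-ps1 (3.16-fold), the uncharacterised 2010106E10Rik (3.13-fold), Cyp2b10 (2.46-fold), Slc39a5 (2.46-fold) and Otc (2.44-fold) were among the largest falls. Nos2, Il1a and Gabrp rose from, and Gsdmc2, Gsdmc3, Trim30e-ps1, 2010106E10Rik, Cyp2b10 and Otc fell into, the dim range.

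In mutant organoids 10 of 24 lists were called with TNFa, all of them up. NF-kB targets rose (17 of 24 up and 0 down, 18 and 0 over the list alone, median 0.57, adjusted p = 7.7e-31), with Nfkb2 at 2.22-fold and Birc3 at 2.33-fold. Chemokines rose (6 of 11 up and 0 down, the same over the list alone, median 0.68, adjusted p = 3.2e-08), with Cxcl11 at 4.09-fold, from the dim range, and Cxcl16 at 2.44-fold. Antigen presentation rose (6 of 16 up and 0 down, 9 and 0 over the list alone, median 0.25, adjusted p = 1.2e-06), with Psmb9 at 1.52-fold. The antimicrobial and oxidase list also rose (6 of 14 up and 1 down, 7 and 1 over the list alone, median 0.31, adjusted p = 3.2e-08), with Duoxa2 at 3.46-fold and the bactericidal phospholipase Pla2g2a at 2.85-fold. Cell death genes rose (8 of 33 up and 2 down, 9 and 2 over the list alone, median 0.12, adjusted p = 0.00436; adjusted p = 0.181 with an estimated correlation). Tnfsf10 rose 3.80-fold from the dim range and the pyroptosis pore former Gsdmd rose 1.52-fold, while Gsdmc2 and Gsdmc4 fell. Wound-associated and fetal-like genes rose (5 of 26 up and 0 down, 6 and 0 over the list alone, median 0.13, adjusted p = 3.4e-04; adjusted p = 0.251 with an estimated correlation), with the metalloprotease Mmp7 at 2.27-fold, Itgb6 at 2.08-fold and Lama3 at 1.81-fold. Enteroendocrine cell genes rose (4 of 19 up and 0 down, the same over the list alone, median 0.07, adjusted p = 0.0136; adjusted p = 0.251 with an estimated correlation). The risen genes were the serotonin synthesis genes Tph1 (3.35-fold) and Gch1 (1.39-fold) and the hormone genes Cck (1.63-fold) and Gcg (1.44-fold). Tph1 and Gch1 also rose in WT. Cholesterol synthesis rose (2 of 19 up and 0 down, the same over the list alone, median 0.12, adjusted p = 0.00440; adjusted p = 0.518 with an estimated correlation), with the enzyme gene Mvd at 1.31-fold. The distal hindgut list rose (2 of 8 up and 0 down, 3 and 0 over the list alone, median 0.12, adjusted p = 0.0435; adjusted p = 0.251 with an estimated correlation), with Hoxd13 at 1.83-fold. The immune cell list held 3 tested genes, of which the lipopolysaccharide receptor gene Cd14, also expressed in epithelium, rose 1.42-fold and none fell, the same over the list alone (median 0.37, adjusted p = 0.0162; adjusted p = 0.0936 with an estimated correlation).

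The remaining 14 lists were not called in mutant organoids. Guca2b rose 2.41-fold and Guca2a 2.00-fold within an absorptive list of mixed sign (5 of 28 up and 3 down, adjusted p = 0.219, or 0.0377 without mutant 2). Of 19 stem cell and Wnt targets 3 rose, among them Cd44 (1.60-fold) and the transcription factor Sox9 (1.38-fold), and the list had adjusted p = 0.0605, or 0.0307 to 0.0461 and so a call without 5 of the 16 arrays in turn, WT + TNFa 2 among them (0.0375). In the goblet list 1 of 25 rose and 0 fell (median −0.06, adjusted p = 0.215). In the small intestine and Paneth cell list 2 of 19 rose and 0 fell (median −0.03, mean 0.05, adjusted p = 0.808), namely the pentraxin Mptx2 (1.42-fold) and the alpha-defensin Defa31 (1.70-fold). The interferon list had adjusted p = 0.146 with 1 of 16 genes up, proliferation 0.0696 with 0 of 30 and p53 targets 0.888 with 0 of 20. Proliferation was called as higher without mutant + TNFa 2 (0.00922), mutant 3 (0.0291), mutant 4 (0.0206) or WT + TNFa 2 (0.0462). The AP-1, ATF and MAPK feedback list had 0.753 with 1 of 30 up and the stress response list 0.461 with 1 of 28 down. With array weights 1095 genes were called in place of 704, and the cholesterol list lost its call without array mutant 2 (adjusted p = 0.0767). The hindgut list lost its call without mutant + TNFa 2 (adjusted p = 0.163), mutant 2 (0.0683), mutant 4 (0.0503) or WT + TNFa 4 (0.0541), and Defa31 without 5 of the 16 arrays in turn, with adjusted p up to 0.0834.

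The TNFa effects in WT and in mutant were much alike. Across 11766 genes the log2 changes correlated at r = 0.733 (Spearman 0.436), with no array shared between the effects, and genes are not independent replicates. In both genotypes 287 genes rose and 222 fell, 0 genes moved in opposite directions, and independent lists would share 20.8 rising and 16.7 falling genes. Of the 1269 genes called in WT, 94.6% had the same sign in mutant, and of the 704 called in mutant 97.0% had the same sign in WT. For 52 genes that rose at least 2-fold on average over both genotypes the median change was 1.29 log2 in WT and 1.33 in mutant (29 genes larger in mutant, 23 in WT, median difference 0.04, adjusted p = 0.344). For 20 such falling genes the medians were −1.29 and −1.17 (17 larger in WT, median difference 0.22, adjusted p = 0.200). Among the 8 genes that rose at least 4-fold all rose more in mutant, 1.93 against 2.32 log2 (median difference 0.47, adjusted p = 0.00761). Over the 5 of them with no group in the dim range, a setting chosen after the values were seen, the median difference was 0.42 (adjusted p = 0.0333). For Nos2 and Tnf the treated levels were 0.01 and 0.06 log2 apart, and for Cp and Ecscr the mutant level was still 0.31 and 0.92 log2 lower with TNFa, so for these genes the larger rise started from a lower untreated level (by 0.56, 0.54, 0.83 and 0.96) and did not lead to a clearly higher treated one. For the other 4 genes the treated level was 0.08 to 0.65 log2 higher in mutant.

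**Figure D1:**
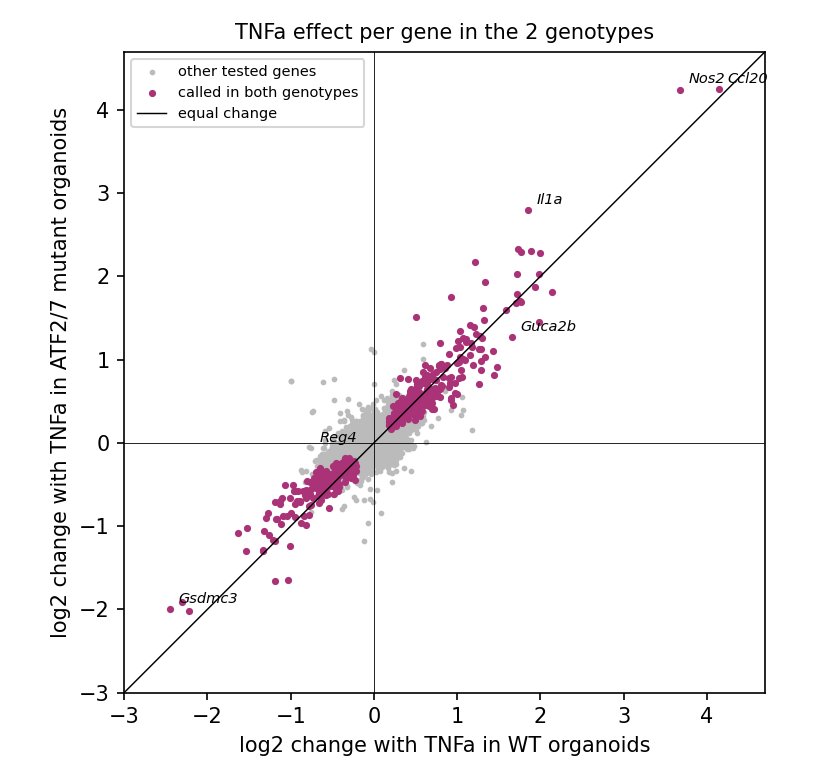
Log2 change with TNFa in WT (x) against that in mutant (y) for each tested gene, purple where called in both genotypes, with the line of equal change. Ccl20 lay at 4.15 and 4.25, Nos2 at 3.67 and 4.24 and Reg4 at −0.75 and −0.07.

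Without TNFa, mutant organoids differed from WT in a small set of genes, some of them by large amounts. Ctla2a, a cysteine protease inhibitor, was 10.3-fold lower (−3.37 log2, SE 0.40, adjusted p = 1.1e-04, n = 4 per group), from 7.66 ± 1.19 in WT to 4.29 ± 0.23 log2, deep in the dim range. Ttc21b, a gene of transport within cilia, was 7.84-fold lower (−2.97 log2, SE 0.22, adjusted p = 5.1e-07) and Fn1, which encodes fibronectin, 7.21-fold lower (−2.85 log2, SE 0.34, adjusted p = 1.1e-04), and both were dim in mutant (5.69 ± 0.61 and 5.46 ± 0.26 log2). The hair keratin Krt36 was 4.82-fold higher (2.27 log2, SE 0.28, adjusted p = 1.1e-04) and the homeobox gene Hoxb6 3.66-fold higher (1.87 log2, SE 0.13, adjusted p = 4.9e-07), both from the dim range in WT. In all, 118 genes were higher in mutant and 174 lower, with 18 each at least 2-fold. Of 19 named differences of that size 9 had a group in the dim range, those of Meis2, Ppef1, Krt84 and Gml2 among them. The homeobox gene Meis2 (3.55-fold), the lectin-like Clec2f (3.51-fold), the phosphatase Ppef1 (3.22-fold), the hair keratin Krt84 (2.93-fold) and the calcium-binding S100g (2.81-fold) were also higher. Ddah1, which degrades inhibitors of nitric oxide synthase (4.64-fold), the Ly6-like genes Gml (3.14-fold) and Gml2 (2.87-fold), the axon guidance gene Sema6d (3.10-fold) and Clu, the chaperone clusterin (3.03-fold), were lower.

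Of 24 lists, 6 were called between untreated genotypes, 3 higher and 3 lower in mutant, and 1 of them held with an estimated correlation. That one, distal hindgut patterning, was higher (3 of 8 up and 1 down, 4 and 1 over the list alone, median 0.29, adjusted p = 9.9e-05). Hoxd10 was 2.55-fold, Hoxd11 2.43-fold and Hoxd13 2.00-fold higher, while the intestinal identity gene Cdx2 was 1.44-fold lower (−0.52 log2, adjusted p = 0.0158). Hoxd10, Hoxd11, Hoxd13 and Ttc21b lie near Atf2, and Krt84 lies near Atf7. In a test chosen after these values were seen, using the gene order of assembly GRCm38.p6, 14 of the 100 tested genes nearest to Atf2 were called in either genotype comparison, against 4.05% of genes elsewhere. The AP-1, ATF and MAPK feedback list was lower (1 of 30 up and 2 down, 1 and 5 over the list alone, median −0.11, adjusted p = 0.00599; adjusted p = 0.181 with an estimated correlation). Jun, an AP-1 subunit gene whose promoter ATF2 binds, was 1.48-fold lower (−0.56 log2, SE 0.08, adjusted p = 8.6e-04). The unfolded protein and integrated stress response list was lower (0 of 28 up and 2 down, 0 and 5 over the list alone, median −0.08, adjusted p = 6.3e-04; adjusted p = 0.133 with an estimated correlation). The lower members were the ATF4 targets Mthfd2 (1.41-fold, adjusted p = 0.0217) and Chac1 (1.25-fold, adjusted p = 0.0237). Cholesterol synthesis was lower (0 of 19 genes passed, 0 up and 3 down over the list alone, median −0.08, adjusted p = 3.4e-04; adjusted p = 0.369 with an estimated correlation). Stem cell and Wnt targets were higher as a list (0 of 19 up and 1 down, 1 and 1 over the list alone, median 0.10, adjusted p = 0.0187; adjusted p = 0.102 with an estimated correlation). The member that moved, the water channel Aqp4, was 2.52-fold lower. Proliferation genes were higher by a median of 0.06 log2 with 0 of 30 past the threshold (adjusted p = 0.0461; adjusted p = 0.888 with an estimated correlation).

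Inflammatory lists were not called between untreated genotypes by camera. NF-kB targets had adjusted p = 0.589 (1 of 24 up), chemokines 0.386 (1 of 11 down), the interferon response 0.714 (0 of 16) and antigen presentation 0.902 (0 of 16). The chemokine list was lower in mutant by fry (mean −0.12 log2, adjusted p = 0.0106). Antimicrobial genes had adjusted p = 0.973 (1 of 14 up and 1 down), cell death 0.463 (0 of 33), p53 targets 0.936 (0 of 20), wound-associated genes 0.373 (2 of 26 up and 2 down) and goblet genes 0.714 (1 of 25 up). Reg4 was the goblet gene that passed, 1.49-fold higher (0.58 log2, SE 0.07, adjusted p = 1.1e-04). Enteroendocrine genes (adjusted p = 0.881) and Paneth genes (adjusted p = 0.714) were not called either. Leaving out 1 array ended the call of the stem cell list (mutant 4, adjusted p = 0.0503), of the proliferation list (mutant 3, 0.222; mutant 4, 0.232; WT + TNFa 4, 0.0520; WT 3, 0.601; WT 4, 0.130) and of Cdx2 (mutant 1, 0.0600; WT 1, 0.0501; WT 2, 0.0602). Array weights raised the number of called genes from 292 to 443, and Mthfd2 and Chac1 lost their calls without 5 and 4 of the 16 arrays in turn, with adjusted p up to 0.0770 and 0.0832.

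**Figure D2:**
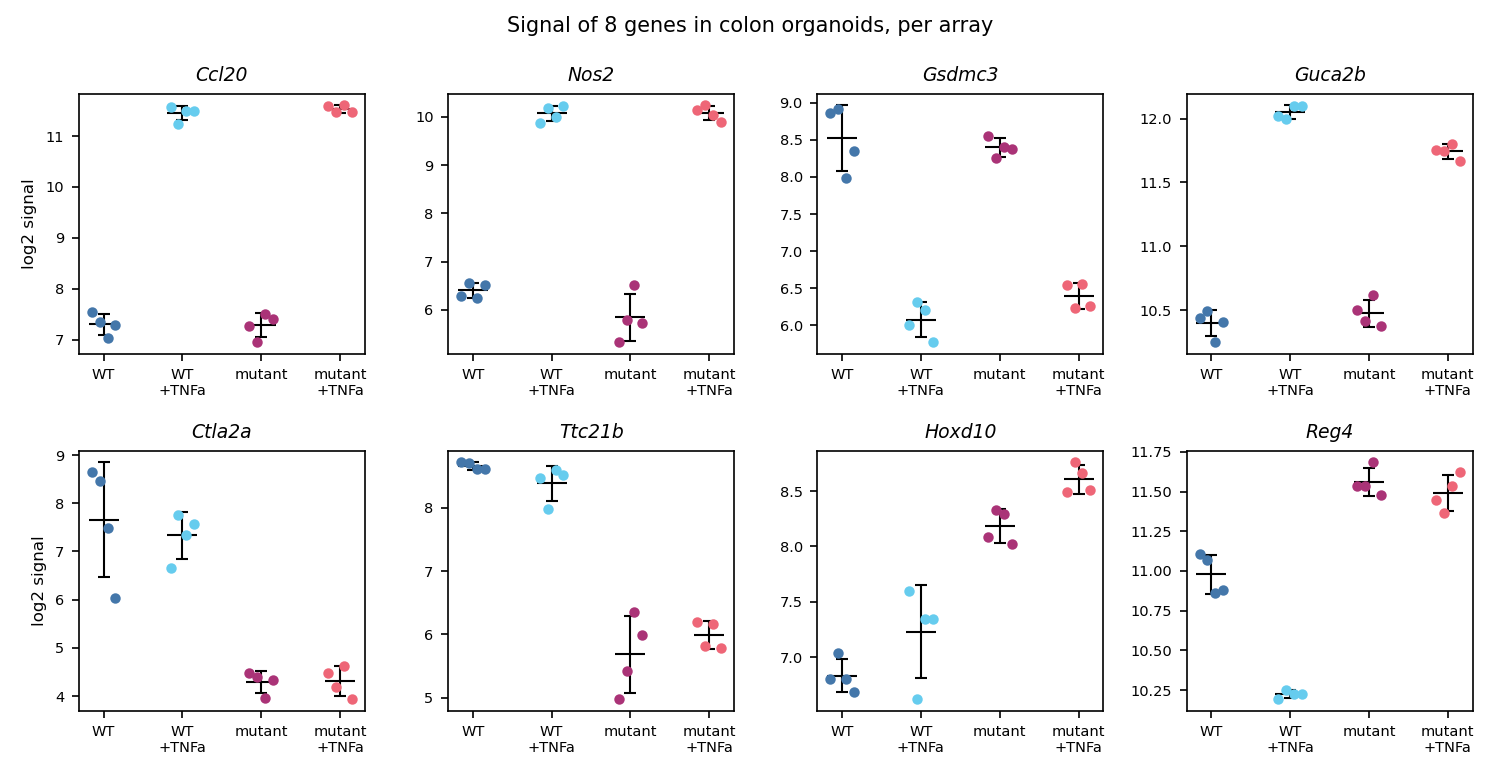
Log2 signal of 8 genes on each array of the 4 groups, with bars for mean ± SD (n = 4). Ccl20, Nos2, Gsdmc3 and Guca2b moved with TNFa, and Ctla2a, Ttc21b, Hoxd10 and Reg4 differed between the genotypes, with Ctla2a at 7.66 ± 1.19 in WT and 4.29 ± 0.23 in mutant.

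With TNFa present, much of the genotype difference was the same. Ctla2a was 8.11-fold lower in mutant (−3.02 log2, SE 0.40, adjusted p = 3.1e-04, n = 4 per group). Fn1 was 6.70-fold lower (−2.74 log2, SE 0.34, adjusted p = 1.7e-04) and Ttc21b 5.26-fold (−2.39 log2, SE 0.22, adjusted p = 6.4e-06). Meis2 was 3.71-fold higher (1.89 log2, SE 0.20, adjusted p = 3.9e-05). Each of these had a group in the dim range. Both genotype comparisons called 123 genes, 63 higher and 60 lower, with 0 opposite and 1.85 and 1.97 expected for independent lists. The effects correlated at r = 0.562 across genes (Spearman 0.290), which are not independent replicates. In all, 184 genes were higher and 133 lower, 23 and 14 of them at least 2-fold. The alpha-defensins Defa17 and Defa3, antimicrobial peptides of Paneth cells, were 4.00-fold higher (2.00 log2, SE 0.33, adjusted p = 0.00225) with identical values in each array, so they count as 1 measurement. Ppef1 (2.73-fold), the adenylate cyclase Adcy8 (2.71-fold), the microtubule gene Mtus2 (2.70-fold), Hoxb6 (2.63-fold) and Hoxd10 (2.60-fold) were higher as well, and of these only Hoxd10 was out of the dim range in treated WT. Ddah1 (4.37-fold), Clu (3.66-fold), Sema6d (2.64-fold), Gml2 (2.52-fold) and Gml (2.35-fold) were lower, and Gml2 was in the dim range in mutant.

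Between the treated genotypes 8 of 24 lists were called, 5 higher and 3 lower in mutant. Enteroendocrine genes were higher (6 of 19 up and 1 down, 8 and 1 over the list alone, median 0.12, adjusted p = 9.9e-05; adjusted p = 0.0629 with an estimated correlation). Gcg, the proglucagon gene, was 2.09-fold higher (1.07 log2, SE 0.11, adjusted p = 3.7e-05), the granule protein gene Scg2 1.78-fold and Tph1 1.75-fold, while the prohormone processing gene Cpe was 1.42-fold lower. Gcg is also a neighbour of Atf2. Small intestine and Paneth cell genes were higher (6 of 19 up and 1 down, 8 and 1 over the list alone, median 0.13, adjusted p = 9.9e-05). Defa31 was 2.39-fold higher, from the dim range in WT, and Lyz1 2.42-fold, and the lower member was the lipoprotein gene Apob. The 6 include both Defa17 and Defa3, and with the defensin and lysozyme copies counted as 1 gene the list lost its call (3 of 15 up and 1 down, mean 0.11 log2, adjusted p = 0.0729). Distal hindgut genes were higher (4 of 8 up and 0 down, 4 and 1 over the list alone, median 0.42, adjusted p = 3.1e-05). Hoxd11 was 1.96-fold, Hoxd13 1.78-fold and Hoxd12 1.65-fold higher, the last from the dim range in WT. Stem cell and Wnt targets were higher (2 of 19 up and 0 down, 5 and 1 over the list alone, median 0.16, adjusted p = 0.00435), with the Lgr5 stem cell marker Smoc2 at 1.34-fold and the growth factor receptor inhibitor Lrig1 at 1.21-fold. Proliferation genes were higher by a median of 0.10 log2 with 0 of 30 past the threshold (adjusted p = 0.0187; adjusted p = 0.860 with an estimated correlation). The interferon response was lower (0 of 16 up and 1 down, the same over the list alone, median −0.07, adjusted p = 0.0199; adjusted p = 0.251 with an estimated correlation), with the antiviral tether Bst2 at 1.23-fold. The p53 list was lower with 0 of 20 genes past the threshold (median −0.08, adjusted p = 0.0381; adjusted p = 0.357 with an estimated correlation). Wound-associated genes were lower (2 of 26 up and 2 down, 2 and 5 over the list alone, median −0.10, adjusted p = 0.0102; adjusted p = 0.475 with an estimated correlation). The YAP target Ankrd1 was 1.31-fold lower, in the dim range in mutant, but the keratin Krt23 was 1.70-fold higher.

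Apart from the interferon response, inflammatory lists were not called between the treated genotypes by camera: NF-kB targets had adjusted p = 0.936 (1 of 24 down), chemokines 0.158 (0 of 11), antigen presentation 0.904 (0 of 16), antimicrobial genes 0.797 (2 of 14 up) and cell death 0.205 (1 of 33 up). Without WT + TNFa 2 the cell death list was called as lower in mutant (mean −0.04 log2, adjusted p = 0.0268). The chemokine list was lower in mutant by fry (mean −0.11 log2, adjusted p = 0.00410). Of 25 goblet genes 3 were higher and 0 lower (median 0.03, adjusted p = 0.0758, or 0.00354 without WT + TNFa 2, 0.0244 without mutant + TNFa 1 and 0.0409 without WT + TNFa 1), and Reg4 was 2.40-fold higher (1.26 log2, SE 0.07, adjusted p = 2.6e-08). The AP-1, ATF and MAPK feedback list had adjusted p = 0.0713 with 1 of 30 down (0.0299 without mutant + TNFa 3 and 0.0435 without WT + TNFa 3), the stress response list 0.201 with 1 of 28 down, and cholesterol synthesis 0.407 with 1 of 19 down. Guca2b was 1.24-fold lower (−0.31 log2, adjusted p = 0.0135). Calls were lost without array WT + TNFa 4 for the interferon (adjusted p = 0.147), p53 (0.198), wound (0.0848) and proliferation (0.0699) lists. They were also lost without mutant + TNFa 1 for interferon (0.0503) and proliferation (0.146), without mutant + TNFa 2 for p53 (0.170) and wound (0.0841), without mutant + TNFa 3 for proliferation (0.0587), without WT + TNFa 3 for p53 (0.0617) and without WT + TNFa 2 for proliferation (0.706). The number of called genes went from 317 to 617 with array weights and to 185 with only the treated arrays. Bst2 and Lrig1 lost their calls without 7 and 4 of the 16 arrays in turn (adjusted p up to 0.0984 and 0.0996), and Guca2b lost its call without mutant + TNFa 4 (adjusted p = 0.0581).

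The TNFa effect differed between the genotypes for 1 gene, Reg4, by limma (855 genes had unadjusted p under 0.05). Reg4 fell with TNFa in WT, from 10.98 ± 0.12 to 10.23 ± 0.02 log2 (n = 4), and stayed level in mutant, at 11.56 ± 0.09 and 11.49 ± 0.11 (change −0.07, adjusted p = 0.763). The difference of the TNFa effects was 0.69 log2, or 1.61-fold (SE 0.10, 95% interval 0.47 to 0.90, adjusted p = 0.0344). As lists, enteroendocrine genes (0 of 19 past the threshold, 8 up and 0 down over the list alone, median 0.19, adjusted p = 2.3e-04; adjusted p = 0.0773 with an estimated correlation) responded more positively in mutant. Their mean signal was 8.11 ± 0.05 log2 in WT, 8.10 ± 0.07 in WT with TNFa, 8.12 ± 0.01 in mutant and 8.33 ± 0.07 in mutant with TNFa. So did small intestine and Paneth genes (0 of 19, 5 up and 0 down over the list alone, median 0.21, adjusted p = 6.3e-04; adjusted p = 0.0309 with an estimated correlation). Their mean went from 8.17 ± 0.09 to 7.84 ± 0.04 in WT and from 8.19 ± 0.04 to 8.24 ± 0.09 in mutant. With the defensin and lysozyme copies counted as 1 gene the Paneth list lost its call (mean difference 0.38 before and 0.12 after, adjusted p = 0.138). Goblet genes (1 of 25 up, Reg4; 2 up and 1 down over the list alone; median 0.07, adjusted p = 0.00487; adjusted p = 0.454 with an estimated correlation) were also called. So were cholesterol synthesis genes (0 of 19, 0 over the list alone, median 0.09, adjusted p = 0.0410; adjusted p = 0.714 with an estimated correlation). None of the inflammatory lists was called for a difference of TNFa effects with all arrays. Called only with an array left out were the p53 list, lower without WT + TNFa 2 (adjusted p = 0.0176, against 0.0879 with all) or 3 others in turn, and the wound list, lower without WT + TNFa 2 (0.0271, against 0.239) or mutant 1 (0.0407). So were the interferon list, lower without mutant + TNFa 3 (0.0392, against 0.138) or WT + TNFa 3 (0.0481), and the stress response list, higher without mutant 3 (0.0292, against 0.113) or mutant + TNFa 2 (0.0496). Without 11 of the 16 arrays in turn Reg4 lost its call (adjusted p 0.0174 to 0.138, log2 difference 0.64 to 0.73), and it kept it only without WT 3, WT 4, WT + TNFa 4, mutant 3 or mutant + TNFa 2. Reg4 also lost its call with each replicate block. The goblet list lost its call without WT + TNFa 3 (adjusted p = 0.0735) or WT + TNFa 4 (0.0541), and the cholesterol list without 9 of the 16 arrays in turn, WT + TNFa 2 among them (adjusted p = 0.0750; up to 0.305).

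**Figure D3:**
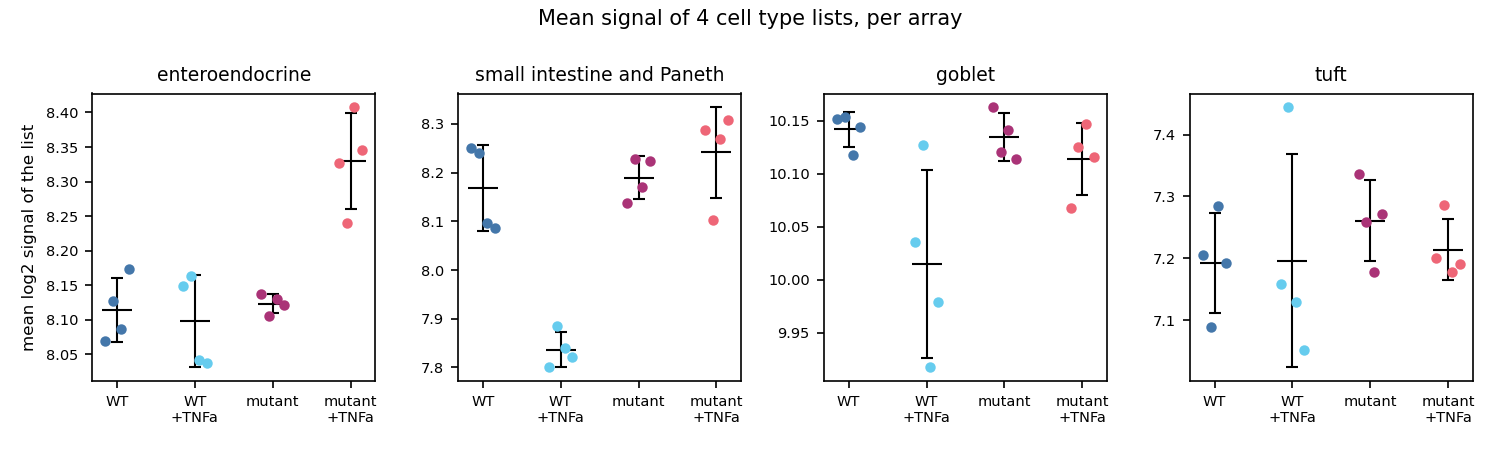
Mean log2 signal of 4 gene lists on each array of the 4 groups, with bars for mean ± SD (n = 4). Small intestine and Paneth genes were lowest in WT with TNFa (7.84 ± 0.04), enteroendocrine genes highest in mutant with TNFa (8.33 ± 0.07), and array WT + TNFa 2 is among the dots of its group.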

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

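The tests of marker genes in array WT + TNFa 2, of the lists without that array and of the secretory share were chosen only after the results were seen, and the other tests in this part before.

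Array WT + TNFa 2 was far from the other arrays of its group. Its gap to the nearest array, as a share of the group's range, was 0.875 for the array median (7.11 log2) and 0.840 for the mean correlation with the group (0.977). A weaker TNFa response in that sample could not be decided: the slope of its deviation on the TNFa effect was −0.22, against −0.10 to 0.15 for other arrays, and a slope under −0.3 had been asked for. The distribution of its signals was ruled out as the whole cause, since the SD of its deviation stayed at 0.279 log2 after quantile normalization, against at most 0.177 for the other arrays. RNA from mesenchymal, immune or endothelial cells stays open: the median deviations of 0.106 log2 for fibroblast, 0.219 for immune and 0.25 for endothelial markers were the highest of the 16 arrays (at most 0.091, 0.136 and 0.127 in others), yet many of these markers are dim. No biological explanation was tested, since the labels set the sample apart in nothing.

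Reg4 and 4 lists were called for a difference between the genotypes in their TNFa effect by a direct test. Reg4, the secretory cell lectin, differed by 0.69 log2, and the mean over the list by 0.38 for small intestine and Paneth genes, 0.22 for enteroendocrine genes, 0.11 for goblet genes and 0.092 for cholesterol synthesis genes. With an estimated correlation only the Paneth list kept its call, at adjusted p = 0.0309, against 0.0773 for enteroendocrine, 0.454 for goblet and 0.714 for cholesterol synthesis genes.

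Technical explanations were weighed for the Paneth, enteroendocrine and goblet lists. Array WT + TNFa 2 did not cause them, since without it the highest adjusted p of these lists was 2.3e-04. The Paneth call rested on the defensin and lysozyme copies, 5 of which were in the list. With 16 such genes counted as 1, the list went from 19 to 15 genes and its adjusted p to 0.138. Its mean difference went from 0.38 to 0.12 log2 and the SD of its members from 0.61 to 0.24. The merged copies still differed by 0.74 (SE 0.19, adjusted p = 0.333 over all genes). Merging has the same effect on copies that share probes and on copies that move together, so shared probes stay open. A larger share of every secretory cell type could not be decided. The difference of TNFa effects was 0.151 log2 larger for the enteroendocrine list than for the goblet and tuft genes together (SE 0.055). Without the array it was 0.125 larger (SE 0.053). The tuft list differed by −0.05 (SE 0.10), or 0.033 without the array, where the goblet list differed by 0.14. The lists lie at unlike signal levels, in WT 10.14 log2 for goblet and 7.19 for tuft. An equal rise in share need not move them by equal amounts. For the enteroendocrine list the genotype stays open, and chance was not tested for single lists.

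Of 572 sets of 4 arrays, 1 for each named gene in each group, 24 held an array far from the rest. When the sets for the array measures were added, 26 were found, or 4.48% of all sets together, and chance alone gives about 1 in 20. The gap of the far array as a share of the group's range is given for each. In mutant these were Gpx2 (mutant 1, 0.984), Clca4b (mutant 2, 0.951), Sema6d (mutant 4, 0.921), Mmp7 (mutant 1, 0.900), Tjp3 (mutant 3, 0.897), Defa17 and Defa3 (mutant 1, 0.876 each), Ang4 (mutant 1, 0.866), Ecscr (mutant 2, 0.857) and Cxcl16 (mutant 2, 0.837). In mutant with TNFa they were Cldn8 (mutant + TNFa 4, 0.941), Pmaip1 (mutant + TNFa 2, 0.923), Lama3 (mutant + TNFa 3, 0.898), St6galnac1 (mutant + TNFa 3, 0.897), Cxcl16 (mutant + TNFa 4, 0.893), Cyp2b10 (mutant + TNFa 4, 0.880), Slc10a2 (mutant + TNFa 3, 0.873), Mylk (mutant + TNFa 4, 0.871), Cxcl11 (mutant + TNFa 3, 0.844) and Ier3 (mutant + TNFa 1, 0.844). In WT with TNFa they were Mvd (WT + TNFa 4, 0.930), Sema6d (WT + TNFa 4, 0.847) and Cyp2c55 (WT + TNFa 2, 0.832), and in WT Cd14 (WT 1, 0.947).

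Probe sets without a gene name also carried signal. Of 550 tested, TNFa moved 62 in WT (33 up, 29 down) and 43 in mutant (29 up, 14 down), and the genotypes differed in 17 without TNFa (7 up, 10 down) and 14 with it (10 up, 4 down). The largest change was that of TC1700002352.mm.2, by 3.82 log2 in WT and 4.10 in mutant (SE 0.11). TC1000000717.mm.2 was 0.95 log2 lower in mutant without TNFa (SE 0.17).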

How the results depend on the processing

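The settings without array WT + TNFa 2 and over genes with no dim group, and the Paneth list with its copies merged in the simple comparisons, were chosen only after the values were seen. Of 232 calls of named genes 182 held in every setting that kept the gene, with the 2-fold minimum left out of the count. These genes had been named for large changes or small p in the same data. Of 37 calls of lists 14 held in every setting counted for lists. Merging the Paneth copies was not counted, and it ended the calls of that list between treated genotypes and for the difference of TNFa effects. The mean of the proliferation list between untreated genotypes turned from 0.05 to −0.0064 log2 without WT 3 (highest 0.098, without WT 2), and no other called gene or list changed sign. For named genes, 263 of the results with 1 array left out and 112 of the others were no longer called, and for lists 33 and 40 besides that one. The cause of changes that the setting itself does not explain was not tested.

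Gene counts for the TNFa effect in WT, in mutant and for the genotype effect without and with TNFa were 1269, 704, 292 and 317. At least 2-fold changes left 88, 68, 36 and 37, with array weights there were 1095 in mutant and 443 and 617 for the genotype effects, and fitting only the groups compared gave 720 in WT and 185 between treated genotypes. With 1 array left out the counts ran from 955 to 1430, 504 to 900, 198 to 435 and 192 to 340, the upper ends each without WT + TNFa 2. The 1 gene that differed in its TNFa effect became 3 with the stricter filter, 5 with trend and robust fitting, 3 with array weights, 0 at 2-fold, 0 without WT + TNFa 2, and 0 to 4 with 1 array left out. Another scaling moved the counts little (median centred 1301, 713, 270 and 323).

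Lists called were 9, 10, 6, 8 and 4 (the last for the difference of TNFa effects). With the estimated correlation 5, 4, 1, 3 and 1 were left, and fry gave 11, 11, 5, 5 and 2. With 1 array left out the numbers ran from 8 to 11, 9 to 12, 4 to 7, 4 to 9 and 3 to 5. A list not called with all arrays was called without 1 array in 15 cases, 8 of them without WT + TNFa 2. The correlation of TNFa effects across genes, 0.733, was 0.609 without the filter, 0.436 as Spearman and 0.677 to 0.762 with 1 array left out. The larger rise in mutant was 0.04 log2 at the 2-fold threshold (−0.01 to 0.09 with 1 array left out), −0.02 at the 0.5 log2 threshold (172 genes, adjusted p = 0.941) and 0.47 at 4-fold (0.42 over genes with no dim group), and the smaller fall 0.22 (0.14 to 0.27), or 0.16 at 0.5 log2 (96 genes fell more in WT and 24 in mutant, adjusted p = 0.0717).

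With a replicate block by number, the counts of called genes were 1070, 615, 246, 262 and 0, with a fixed replicate block by genotype and number 876 and 500 for the TNFa effects and 0 for their difference, and with a random one 299 and 312 for the genotype effects and 0. Same-numbered samples did not deviate together: over 16 pairs the correlations ran from −0.31 to 0.25, 3 were over 0.1, and 3 samples matched their own number best, so the number is not taken to pair samples. A random replicate block for lists was not run.

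Dim signal sets the limit for 7084 genes, which were not tested, and leaves 11 of 30, 11 of 30, 9 of 19 and 10 of 22 named changes of at least 2-fold approximate.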

Other observations

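The tests of gene neighbourhood around Atf2 and Atf7, of the Hoxd cluster and of distal origin were chosen only after the result was seen, and the splits before.

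Barrier and transport genes that the comparisons above left aside also moved. Slc9a3, the sodium-proton exchanger of colonocytes, was 2.29-fold lower in mutant without TNFa (−1.20 log2, SE 0.15, adjusted p = 1.1e-04, n = 4 per group) and 2.03-fold lower with it. With all arrays the absorptive colonocyte list was not called (2 of 28 down, adjusted p = 0.101, and 2 up and 3 down, adjusted p = 0.285). Without TNFa it was called as lower when mutant 1 (adjusted p = 0.0290), mutant 2 (0.0103), WT 1 (0.0307) or WT 2 (0.0247) was left out. In junctions and barrier the pore-forming claudin Cldn15 fell 1.35-fold and the sealing claudin Cldn8 1.36-fold with TNFa in WT (3 of 25 up and 3 down, adjusted p = 0.936), and 1.28-fold and 1.35-fold in mutant (2 up and 2 down, adjusted p = 0.986). Cldn15 was also 1.28-fold lower in mutant without TNFa and 1.20-fold lower with it, the only junction gene called (adjusted p of the list 0.761 and 0.648). Of 23 oxidative stress and glutathione genes, 1 rose and 5 fell with TNFa in WT (adjusted p = 0.105) and 0 rose and 4 fell in mutant (adjusted p = 0.0614). The glutathione transferase Gstm3 fell 1.57-fold in WT and 1.37-fold in mutant. The retinal dehydrogenase Aldh1a1 fell 1.40-fold and 1.53-fold, into the dim range in both genotypes. Without 1 array that list was called as lower, in WT without WT + TNFa 3 (adjusted p = 0.0210) and in mutant without mutant 3 (0.0421), mutant 4 (0.0366) or WT 2 (0.0432). Between the genotypes 0 of its genes passed over all genes, and over the list alone 1 was higher in mutant with TNFa.

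Few genes passed in the lists of tuft and of non-epithelial cells, of which only the immune cell list was called, with TNFa in mutant (median 0.37 log2, adjusted p = 0.0162). None of 7 tested tuft cell genes passed in any comparison, and neither did the 1 tested endothelial and glial gene. Of 7 fibroblast and smooth muscle genes only Fn1 passed, in the genotype comparisons, where the median was −0.03 log2 and the mean −0.40 without TNFa (adjusted p = 0.503). Of 3 immune cell genes, Cd14 rose 1.47-fold and Lyz2 fell 1.67-fold with TNFa in WT, and between treated genotypes Lyz2 was 2.38-fold higher and Cd14 1.15-fold lower in mutant. The fall of Lyz2, which can share probes with Lyz1, lost its call without 4 of the 16 arrays in turn (adjusted p up to 0.0826), and the lower Cd14 without 5 (up to 0.0959). The sex-linked genes Eif2s3y (3.45 to 4.75 log2) and Uty (2.61 to 3.07) were dim on all 16 arrays, so they do not tell the sex of any sample.

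Genes that differed between the genotypes clustered around Atf2: 14 of 100 neighbouring tested genes were called, 9 higher and 5 lower in mutant, among them Gcg, Ttc21b, Itga6, Pdk1 and Hoxd10 to Hoxd13. DNA flanking the targeted Atf2 allele, carried along from another mouse strain, may explain this. That 0% of 9581 windows elsewhere held as many called genes (highest 11) shows the cluster itself, and does not tell such DNA from a regional effect of the mutation. The Hoxd cluster alone does not, since without it 10 were called and 0.710% of windows held as many. DNA flanking the targeted Atf7 allele showed no such excess (2 of 58 called, 66.6% of windows held as many). Krt84 was 1 of these 2, and a count does not clear single genes. A more distal origin of the mutant organoids would raise the other posterior Hox genes. The 4 tested had a median difference of 0.0080 log2 against 0.98 for Hoxd10 to Hoxd13, which argues against it only as far as these 4 genes go. Outside that window Hoxb6 and Meis2 were higher in mutant in both comparisons, and Cdx2 was lower without TNFa. Whether the organoids differed in regional origin in another way was not tested. A regional or direct effect of the genotype stays open as the biological explanation, untested.

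Splits of the same samples into other groups show what chance can give. For called genes a random division of these arrays can be excluded in the simple comparisons. Only 1 of 35 splits, the real one, reached 1269 in WT (highest other split 3), 704 in mutant (0), 292 between untreated genotypes (1) and 317 between treated genotypes (1). That is the lowest share such splits can give. The splits take the arrays as independent, which no label shows, so a chance difference between animals or organoid lines is not excluded. For the difference of TNFa effects 2 of 100 splits, the real one included, called 1 gene or more. That share is low, but the highest other split called 10 genes, more than the real one. The count therefore does not set the genotypes apart, and chance is not taken as excluded. Splits that exchange unequal numbers of arrays among the treated and the untreated carry part of the genotype effect into the difference. Such a split can call genes for that reason, so these 100 splits are no clean measure of chance. The same limit holds where they are used below for lists and for size. Structure among the samples was not tested. For the number of called lists chance cannot be excluded, and single lists were not tested this way: 7 of 35 splits reached 9 in WT (highest other split 10), 4 reached 10 in mutant (13), 3 reached 6 between untreated genotypes (7), 2 reached 8 between treated genotypes (8), and 24 of 100 reached 4 for the difference (8). Nor can it for the size of the TNFa response, with 57 of 100 splits as large as 0.04 for the rises (highest other 0.24) and 7 as large as 0.22 for the falls (0.29). For rises of at least 4-fold, 3 of 100 were as large as 0.47, but the highest other split gave 0.55. That test covers 8 genes and was not adjusted for the other tests of size, so chance is not taken as excluded there either.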
